A study of Apis mellifera with 20 samples.

How the data were processed

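The series profiled N6-methyladenosine (m6A), a methyl mark on adenosines inside messenger RNA, in honeybee (Apis mellifera) larvae. It holds 20 libraries from 5 kinds of larvae: larvae of instar 1 (L1), from which either caste can still develop, and queen and worker larvae of instars 3 (L3) and 5 (L5). Each kind has 2 replicates of an immunoprecipitated library (IP) and 2 of an input library. Per the labels' protocols, polyadenylated RNA was fragmented, fragments were pulled down with an m6A antibody, and libraries of the pulled-down RNA (IP) and of fragmented RNA without this step (input) were made with the NEBNext Ultra RNA kit, which does not mark strand. The labels do not say whether replicates came from separate colonies or collections, so p-values measure only the spread between these samples, which may be technical.

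Per the file headers, the deposited tables give 1 FPKM value (fragments mapped to a model, scaled for its length and for the mapped fragments of the library) per gene model and library, for 15314 models on 1653 scaffolds, with a scaffold, strand, start and end for each. The submitters' processing notes name HISAT2 2.1.0. The program that computed the FPKM, the genome build and the annotation are not given in the sources used here, so coordinates are quoted as the deposited tables give them, without a build. The depth of each library is unknown: low FPKM values shared no common step from which whole reads could be recovered. A value of exactly 0 can be a failed estimate, so genes at 0 are described as listed at 0. Because the kit does not mark strand, 3345 of the 15314 models that overlap another model are uncertain, among them 24.7% of the genes tested for expression.

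Gene names could not be used. The files give only IDs starting with GB, and 0 of the 15314 IDs matched the 12398 genes of the RefSeq table of assembly Amel_HAv3.1. Lists of genes by function had been fixed before the data were examined; none of their genes could be located, so no list was tested. The rule for named genes, fixed beforehand for this case, took the 2 IDs with the highest and the 2 with the lowest log2 difference among the genes past the threshold in each comparison. As an addition chosen once it was clear that names could not be matched, neighbouring models that changed in the same direction were counted.

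FPKM values were divided by median-of-ratios factors from genes above 1 FPKM in every library of the fit (7511 genes for the input libraries and 6947 for all libraries). Genes with a mean scaled FPKM of at least 1 were kept, and log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend). Log2 differences are on this scale, which understates changes of low genes. Expression was compared in the 10 input libraries (10119 genes) and m6A enrichment, the IP minus input difference, in all 20 libraries (10391 genes). With 1 value per gene model, enrichment is that of whole genes. Single m6A sites cannot be seen, and a change at a site can leave the value of its gene unmoved. None of the 20 libraries is a control pulldown without the m6A antibody, so enrichment is not a measured m6A level. With 2 libraries per group, the spread was pooled over all groups of a fit. P-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Library measures were compared by exact two-sided permutation tests. Figures were drawn with matplotlib 3.10.9.

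The fit was tested on simulated data built from the real group means. The residual spread of the L5 libraries was kept apart from that of L1 and L3, and 200 genes were changed per comparison. Each false share comes from a single simulated run and depends on how many genes change. It is therefore no estimate for the real lists. For expression in L3 queens against workers (9989 genes), 26.3% of changes of 1 log2 unit and 92.9% of changes of 3 units were recovered, and 1.68% of the calls were false. For L5 queens against workers (9914 genes) the recovery was 24% and 89.5%, but 41.6% of the calls were false. The simulated L5 libraries had a wider spread than those of L1 and L3, as the real ones did. The same simulated L5 data gave 5.13% false calls when the L5 libraries were fitted alone. Other false shares with the pooled spread were 24.2% for the caste difference between instars (9919 genes), 17.2% for L5 against L3 in queens (9912 genes) and 10.9% in workers (9978 genes). For m6A they were 4.08% between L3 castes (10330 genes), 49.1% between L5 castes (10321 genes), 16.8% for L5 against L3 in queens (10277 genes) and 11.3% in workers (10287 genes). The pooled m6A fit between L3 castes recovered 6.19% of changes of 1 log2 unit and 90.7% of changes of 3, against 22.9% and 92.8% with the L1 and L3 libraries alone (10019 genes, 5.88% of calls false) and 28.9% and 94.8% with a weight per library (10330 genes, 10.4% false). Fitted alone, the L5 libraries recovered 1.14% and 84.9% for expression (9032 genes) and 0% and 75% for m6A (9807 genes) between castes. The false share with a weight per library was 12.5% between L3 castes (9989 genes), 15% for L3 queens against L1 (10021 genes) and 16.8% for L3 workers against L1 (9993 genes), where the pooled spread gave 2.52% and 3.45% in the comparisons with L1. With the L1 and L3 libraries alone it was 6.88% (9895 genes), 3.27% (9934 genes) and 7.47% (9884 genes) in the same order. After the L5 replicates were seen to differ more than the others, 3 alternatives were added: L1 and L3 libraries alone, L5 libraries alone, and a weight per library. Alternatives listed beforehand were a pseudocount of 0.1, no filter on low values, FPKM as deposited without scaling, a replicate block, and leaving out each replicate in turn.

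The neighbour count took 8370 pairs of adjacent tested models that do not overlap; runs of at least 4 adjacent tested models may include overlapping ones. The count was set against 10000 shuffles of the calls over the genes.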

Results

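Expression and m6A enrichment were measured in 20 libraries of honeybee larvae, with 2 input and 2 IP libraries for each of 5 kinds of larvae (L1, L3 queens, L3 workers, L5 queens and L5 workers). Queens and workers are female castes that develop from alike eggs on different larval diets, and the series asks how m6A differs over larval development and between castes. The input libraries list 8983 to 10564 gene models above 1 FPKM and the IP libraries 8973 to 11604. The summed FPKM was 529489 to 674587 in input and 512177 to 891050 in IP, and read depth is unknown.

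Replicates differed more at L5 than before. Pearson's r between input replicates, across genes, which are not independent replicates, was 0.985 at L1, 0.988 in L3 queens, 0.993 in L3 workers, 0.943 in L5 queens and 0.950 in L5 workers. For the ratio of IP to the input of the same number, a match that the labels do not explain, the replicate r was 0.946, 0.949, 0.932, 0.357 and 0.454 in the same order. Between larvae, this ratio correlated at 0.919 to 0.949 among the L1 and L3 pairs of libraries, at 0.279 to 0.584 between those and the L5 pairs, and at 0.357 to 0.475 among the L5 pairs.

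**Figure D1:**
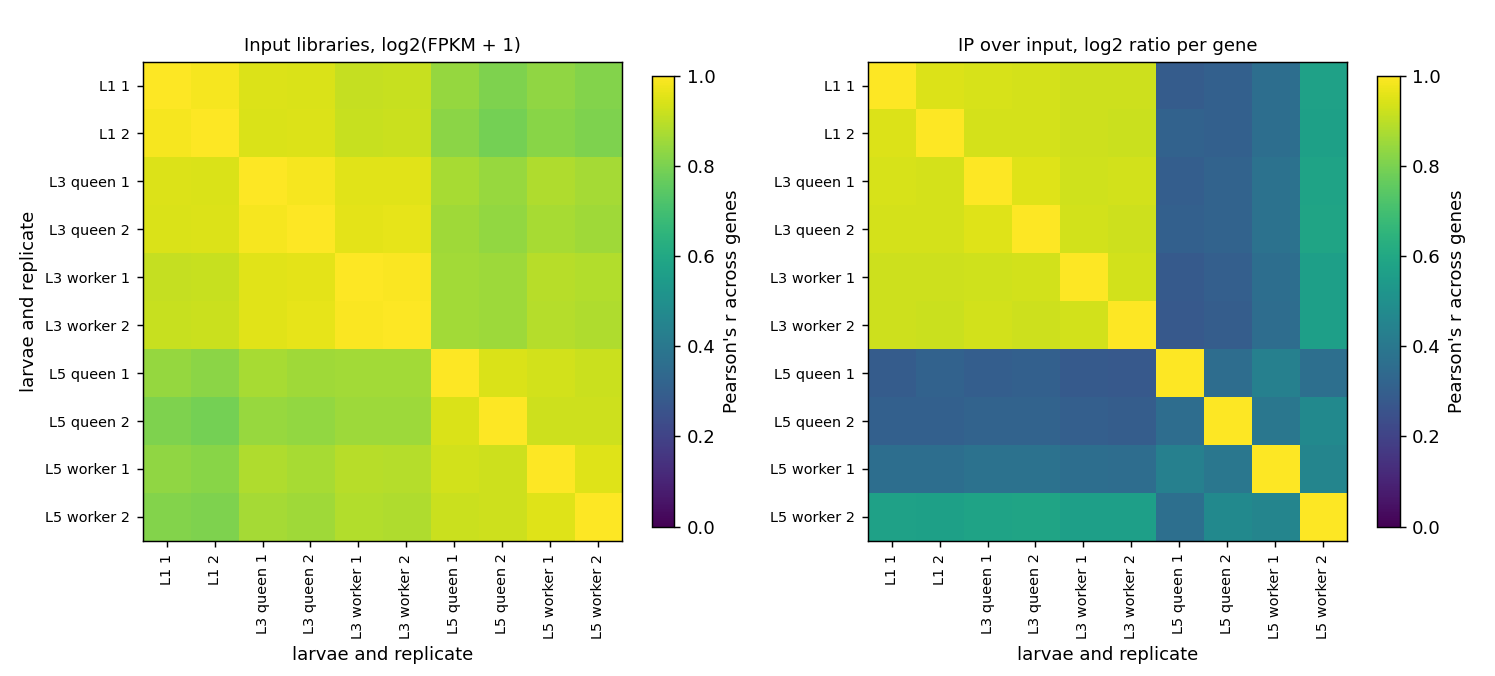
Pearson's r across genes between the 10 input libraries (left, log2(FPKM + 1)) and between the 10 log2 ratios of IP to input (right), with larvae and replicate on both axes and colour giving r from 0 to 1. Ratios of L1 and L3 larvae correlate with each other at 0.919 or more, and with those of L5 larvae at 0.584 or less.

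The model GB43330 (GroupUn98, 15844 to 16065, plus strand) was singled out after its values were seen. It held 34.5% to 47.7% of the summed FPKM in the L1 and L3 IP libraries and 9.56% to 12.4% in the L1 and L3 input libraries. In the L5 libraries it held at most 0.781%.

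In L3 larvae, queens and workers differed in a block of neighbouring models on scaffold Group12.10. GB53623 (101999 to 103006, plus strand) had 762 and 365 FPKM in the 2 queen libraries against 5.2 and 7.24 in workers, a log2 difference of 5.55 ± 0.34 (SE, n = 2 and 2, limma adjusted p = 8.39e-05). GB53621 (96926 to 97927, plus strand) had 583 and 225 FPKM in queens against 5.95 and 4.76 in workers. Both belong to 5 adjacent models between 93729 and 105829 that were all higher in queens, by 2.67 to 5.55 log2 units. In the other direction, GB54419 (Group15.9, 315521 to 316958, minus strand) had 199 and 117 FPKM in queens against 17841 and 16286 in workers, a log2 difference of -7.51 ± 0.38 (SE, n = 2 and 2, limma adjusted p = 3.99e-05). GB50662 (Group13.5, 498272 to 504336, minus strand) had 12.8 and 3.38 FPKM in queens against 1042 and 736 in workers. A further 4 runs of at least 4 adjacent models were all lower in queens: 5 models on Group10.13 (115066 to 153665), 5 on Group14.10 (254907 to 308870), 5 on Group4.6 (402700 to 421657) and 4 on Group8.7 (943783 to 998800).

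Over all genes, 770 of 10119 differed between L3 castes at a limma adjusted p under 0.05, 280 higher and 490 lower in queens. At least a 2-fold difference was seen for 198 of the higher and 387 of the lower genes. The count was 2381 with the L1 and L3 libraries fitted alone, which kept all 770, and 3012 with a weight per library. In simulated data 1.68% of the calls were false with the pooled spread, 6.88% with the L1 and L3 libraries alone and 12.5% with a weight per library. It was 305 and 378 without L3 queen replicates 1 and 2, 253 and 275 without L3 worker replicates 1 and 2, and 1177 and 1175 without L5 queen replicates 1 and 2. With FPKM as deposited the median of all genes shifted by 0.60 log2 units and the split became 2675 higher and 269 lower, so directions are relative to the typical gene.

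In L5 larvae, GB41428 (Group6.20, 1233385 to 1234915, minus strand) had 564 and 541 FPKM in queens against 15.7 and 7.93 in workers, a log2 difference of 5.46 ± 0.24 (SE, n = 2 and 2, limma adjusted p = 6.35e-05). GB40614 (Group12.13, 2366347 to 2371275, minus strand) had 32.6 and 42.5 FPKM in queens, against 0.0296 in 1 worker library and a value listed at 0 in the other. It was also higher in L3 queens, with 118 and 62.3 FPKM against 0.835 and 1.67. GB42557 (Group7.9, 332532 to 334683, plus strand) had 399 and 284 FPKM in L5 workers, against 5.01 in 1 queen library and a value listed at 0 in the other, while every L3 library had 460 to 690 FPKM. GB48492 (GroupUn4341, 183 to 3153, plus strand) had 86.4 and 27.4 FPKM in workers against 0.802 and a value listed at 0 in queens. A run of 4 adjacent models on Group5.18 (100986 to 122967) was lower in L5 queens.

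**Figure D2:**
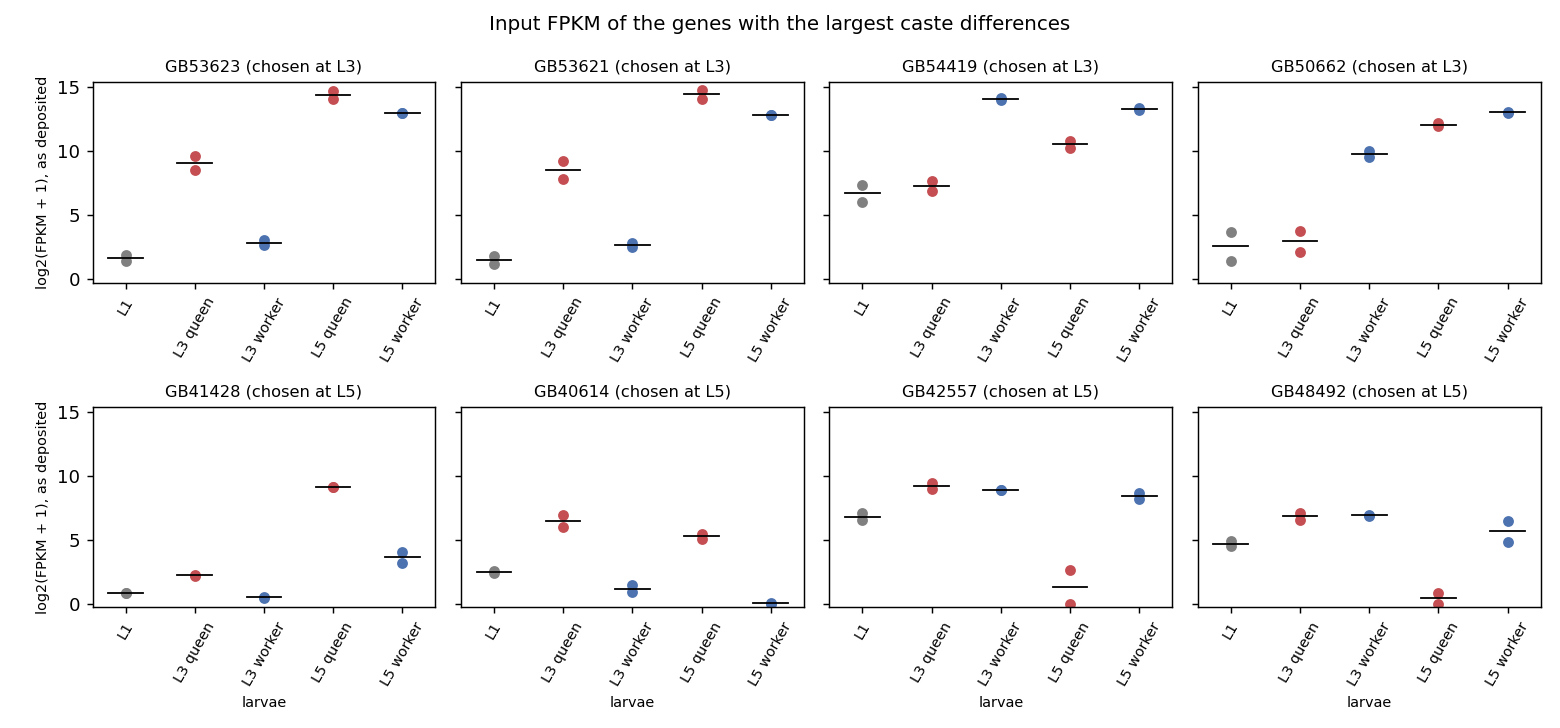
Input log2(FPKM + 1) as deposited, for the 4 genes chosen at L3 and the 4 chosen at L5, in each kind of larvae. Points are single libraries (red queens, blue workers, gray L1) and short lines are means of 2 libraries. GB54419 lies at 17841 and 16286 FPKM in L3 workers and at 199 and 117 in L3 queens.

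At a limma adjusted p under 0.05, 1150 of 10119 genes differed between the L5 castes, 519 higher and 631 lower in queens, but only 77 did (19 higher, 58 lower) when the L5 libraries were fitted alone, and 124 with a weight per library. In simulated data 41.6% of the calls of the pooled fit for this comparison were false, while the fit of the L5 libraries alone had 5.13% false calls but recovered 1.14% of changes of 1 log2 unit and 84.9% of changes of 3. All 77 were among the 1150, and the 4 genes named here passed in both fits. The count was 756 without L3 queen replicate 2, 640 and 654 without L3 worker replicates 1 and 2, and 1746 without L5 queen replicate 1.

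The castes were compared between instars by the interaction, the L5 difference minus the L3 difference. GB47565 (Group16.5, 547499 to 548539, minus strand) had 0.576 and 2.67 FPKM in L3 queens against 207 and 228 in L3 workers, but 472 and 241 against 266 and 253 at L5. GB50662 rose to 4602 and 3872 FPKM in L5 queens against 8561 and 8063 in workers. GB48098 (Group7.24, 858539 to 860387, minus strand) had 15 and 5.41 FPKM in L3 queens against 0.162 and 0.0658 in L3 workers, and 0.239 and a value listed at 0 against 7.33 and 6.63 at L5. GB42557, with the values above, had an interaction of -6.85 ± 1.00 (SE, limma adjusted p = 7.80e-03) and missed the threshold with a pseudocount of 0.1 (limma adjusted p = 0.0537). The interaction passed for 808 genes, 484 with a more positive value at L5 and 324 with a more negative one (limma adjusted p under 0.05), and for 390 with a weight per library.

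In simulated data 24.2% of the calls of the interaction were false. Its count was 476 and 481 without L1 replicates 1 and 2, 262 and 290 without L3 queen replicates 1 and 2, 216 and 178 without L3 worker replicates 1 and 2, and 1762 without L5 queen replicate 1. On the FPKM as deposited it was 1338, 193 more positive and 1145 more negative, after a shift of the median of all genes by -0.55.

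Calls of the castes were compared between the instars. The lists come from 1 fit with a spread per gene in common, so independent lists are a reference and not the value without a shared change, and the excess was not tested. Of the genes lower in queens, 143 were shared by L3 and L5, against 30.6 for independent lists, and of those higher in queens 29 were shared, against 14.4. Opposite calls numbered 25 and 35, against 17.5 and 25.1. Across all genes the log2 differences of the 2 instars correlated at r = 0.18. The shared calls in the same direction, 172 in all, numbered 70 with a weight per library, 89 and 99 without L3 queen replicates 1 and 2, 66 and 70 without L3 worker replicates 1 and 2, and 274 without L5 queen replicate 2.

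From L1 to L3, a region of scaffold Group15.14 fell in both castes. GB50579 (663088 to 663932, plus strand) fell from 1018 and 665 FPKM at L1 to 0.692 and 1.61 in L3 queens and 1.16 and 0.594 in L3 workers. GB50564 (580714 to 581723, plus strand) fell from 812 and 489 FPKM to 1.02 and 1.56 in queens and 1.21 and 0.478 in workers. In queens its call was lost with a pseudocount of 0.1 (limma adjusted p = 0.0768) and without L1 replicate 1 (limma adjusted p = 0.0511). They lie in 9 adjacent models (552773 to 604010) and 6 adjacent models (625623 to 667597) that were all lower than at L1 in both castes. GB51494 (Group3.7, 126382 to 130978, minus strand, overlapping another model) rose in L3 queens from 4.41 and 3.97 to 713 and 701 FPKM, where L3 workers had 15.5 and 12.4. GB51696 (Group8.21, 111563 to 115804, minus strand) rose in L3 workers from 103 and 44.2 to 11817 and 10692 FPKM. GB54419 and GB53623 were the other genes named for workers and for queens.

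L3 queens differed from L1 in 871 genes (472 higher, 399 lower) and L3 workers in 1955 (1117 higher, 838 lower), by limma at an adjusted p under 0.05. With the L1 and L3 libraries alone the counts were 2231 and 4155, and with a weight per library 2050 and 4519. In simulated data the false shares for queens and workers were 2.52% and 3.45% with the pooled spread, 3.27% and 7.47% with the L1 and L3 libraries alone, and 15% and 16.8% with a weight per library. For queens the count was 331 and 366 without L1 replicates 1 and 2, 331 and 392 without L3 queen replicates 1 and 2, and 569 and 572 without L3 worker replicates 1 and 2. For workers it was 904 and 940 without L1 replicates 1 and 2, and 721 and 829 without L3 worker replicates 1 and 2. With FPKM as deposited the splits were 345 higher and 798 lower in queens and 444 higher and 5528 lower in workers, after shifts of the median of all genes by -0.26 and -0.86.

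Between L3 and L5, GB45614 (Group16.6, 3315 to 4251, plus strand) appeared in both castes. It was listed at 0 in both L3 worker libraries and 1 L3 queen library, at 0.594 FPKM in the other, and at 8026 and 10616 FPKM in L5 queens and 3804 and 3117 in L5 workers. GB47546 (Group16.5, 802418 to 804626, minus strand) rose in queens from 0.946 and 1.01 to 2435 and 1998 FPKM. GB53624 (Group12.10, 104801 to 105829, plus strand) rose in workers from 5.32 and 5.2 to 6634 and 8443 FPKM. It is the last of 6 adjacent models from 83985 on that rose in both castes, by a median of 6.02 log2 units in queens and 9.39 in workers. GB51373 (Group10.22, 76940 to 78265, minus strand) fell in queens from 377 and 764 FPKM to 0.251 and a value listed at 0, and in workers from 167 and 218 to 1.56 and 0.663. GB52202 (Group6.14, 563887 to 564946, plus strand) fell in queens from 5912 and 5812 to 7.71 and 24.8 FPKM. GB56000 (Group3.1, 127459 to 128307, minus strand) fell in workers from 207 and 294 FPKM to 3.62 and a value listed at 0. The longest runs were 9 adjacent models lower in L5 workers on Group9.12 (573015 to 745292) and 8 lower in L5 queens on Group2.5 (75480 to 202360).

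This change took in 4469 genes in queens (1977 higher, 2492 lower) and 3741 in workers (1544 higher, 2197 lower), by limma at an adjusted p under 0.05. Of these, 1016 rose and 1450 fell in both castes, against 302 and 541 for independent lists, and 50 and 45 went opposite ways. The log2 changes of the castes correlated at r = 0.72 across genes. Here too independent lists are only a reference, and the excess was not tested. The queen count was 2951 and 2703 without L3 queen replicates 1 and 2, and the worker count 2043 and 1853 without L3 worker replicates 1 and 2. Calls shared in the same direction, 2466 in all, numbered 1473 and 1378 without L3 worker replicates 1 and 2. In simulated data 17.2% of the queen calls and 10.9% of the worker calls were false. On the FPKM as deposited the splits were 1167 higher and 3687 lower in queens (median shift -0.39) and 1735 higher and 1665 lower in workers (median shift 0.16). The L5 input libraries listed 4292 to 5430 models at 0, against 2993 to 3822 in those of L1 and L3. Depth is unknown and the labels give no batch, so development cannot be told apart here from how the L5 libraries were made.

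**Figure D3:**
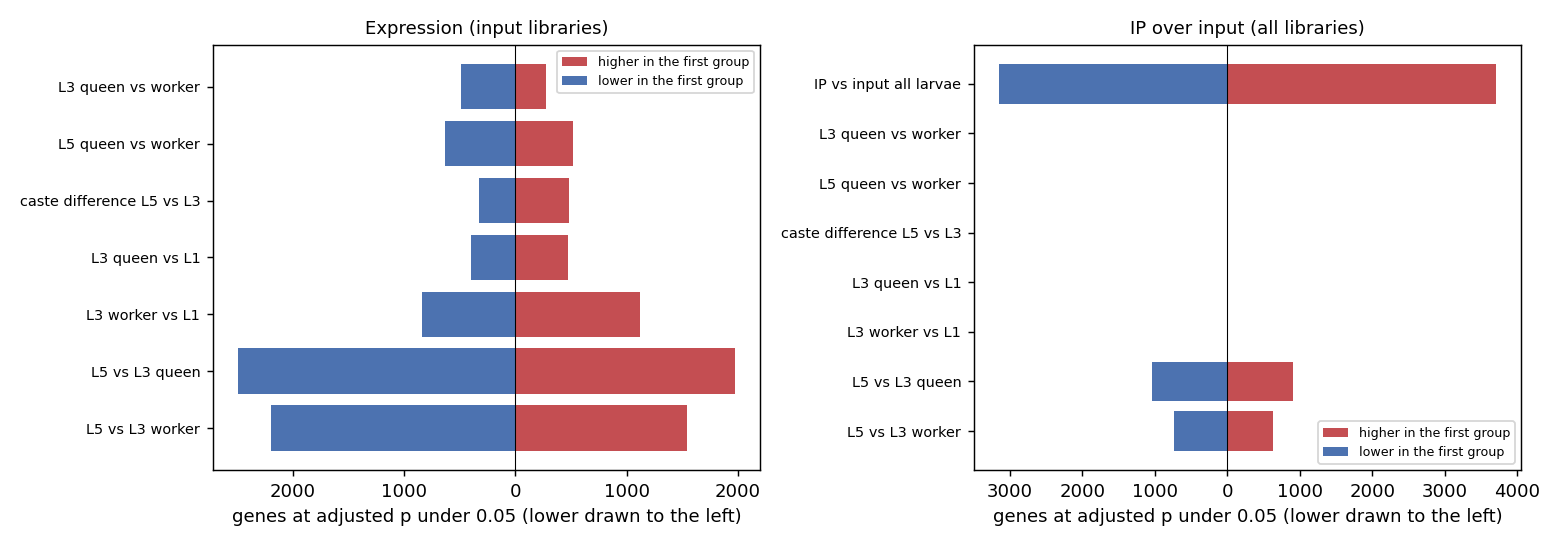
Genes at a limma adjusted p under 0.05 in each comparison, for expression (left) and IP over input (right), with genes higher in the first-named group drawn to the right and lower ones to the left. The change from L3 to L5 holds 4469 genes in queens for expression and 1951 for IP over input, while 770 and 0 passed between the L3 castes. The spread was pooled over all groups and was too wide for IP over input between L3 castes, so that 0 does not show an absence of difference.

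Neighbouring models changed in the same direction more often than shuffled calls. Between L3 castes 114 adjacent pairs did, against a mean of 26.0 and a highest of 51 over 10000 shuffles, and between L5 castes 115 did, against 54.5 and 84. From L1 to L3 there were 121 pairs in queens (31.1 shuffled) and 335 in workers (159 shuffled), and from L3 to L5 1115 in queens (826 shuffled) and 865 in workers (589 shuffled). All 6 comparisons gave a permutation p of 1e-04, the smallest that 10000 shuffles can give. The shuffles treat genes as independent, but neighbours can vary together between replicates. The 5 models on Group12.10 summed to 2454 and 1056 FPKM in the 2 L3 queen inputs. The p therefore does not measure the spread between replicates, and why neighbours changed together was not tested. For the L5 castes the calls were the 1150 of the pooled fit, against 77 with the L5 libraries alone.

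IP was set against input over all larvae to find the gene models enriched by the pulldown. The ratio is of whole genes, and no control pulldown shows how much of it is due to m6A. GB41192 (Group15.3, 256075 to 256931, minus strand) had 343 to 438 FPKM in the 6 L1 and L3 IP libraries against 7.27 to 12.1 in input, and 15.8 to 74.6 in the 4 L5 IP libraries against 5.35 to 9.11. Its log2 enrichment over all larvae was 4.01 ± 0.19 (SE, limma adjusted p = 2.06e-09). GB40846 (Group1.10, 1110370 to 1110654, plus strand) had 912 to 1185 FPKM in the L1 and L3 IP libraries, where 1 input library was listed at 0 and the others had 35.5 to 53.7. At L5 it had 68.5 to 401 FPKM in IP, where 1 input library was listed at 0 and the others had 20.8 to 32.3. GB53730 (Group3.9, 1195806 to 1196058, plus strand) was lower in IP over all larvae, with 4.72 to 14.2 FPKM in L1 and L3 IP against 65.7 to 109 in input. At L5 it had 29.8 and 66.5 FPKM in queen IP against 59.2 and 76.1 in input, and 19.4 and 14.2 in worker IP against 94.3 and 76.0 in input. GB48867 (Group5.4, 341824 to 344300, minus strand, overlapping another model) had at most 0.748 FPKM in L1 and L3 IP against 3.78 to 7.04 in input, and 1.71 to 5.18 in L5 IP against 10.03 to 18.5.

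Over all larvae, 6862 of 10391 genes differed between IP and input, 3710 higher and 3152 lower in IP, of which 1369 and 430 by at least 2-fold (limma adjusted p under 0.05). Enrichment was highest in the models of the longest genomic span, but across all genes span and ratio were weakly related: Spearman's rho was 0.133 to 0.154 in the L1 and L3 larvae, 0.0881 in L5 queen replicate 1 and -0.0253 to -0.0145 in the other L5 larvae. Of the 194 models spanning over 64 kb, 64.4% were higher and 4.64% lower in IP. Their median log2 ratio was 0.72 at L1, 0.67 in L3 queens, 0.60 in L3 workers, 0.42 in L5 queens and 0.48 in L5 workers. The 4714 models of 1 to 4 kb had medians of -0.19, -0.18, -0.22, 0.06 and 0.04. The 1354 models under 1 kb had medians of 0.04 at L1, 0.02 in L3 queens, -0.0044 in L3 workers and 0.25 and 0.35 in L5 queens and workers, above the 0.08 and 0.04 of the 3319 models of 4 to 16 kb at L5. The ratio fell with input abundance, which enters it as the divisor, with a rho of -0.209 to -0.181 in the L1 and L3 larvae and -0.299 to -0.223 in the L5 larvae. The 308 genes above 256 FPKM had medians of -0.48 at L1, -0.60 in L3 queens, -0.68 in L3 workers, -0.04 in L5 queens and -0.23 in L5 workers. The 2701 genes under 4 FPKM had medians of 0.21, 0.23, 0.16, 0.41 and 0.48. The majority direction depended on the setting: with the L1 and L3 libraries alone 3738 genes were higher and 4123 lower, with no filter on low values 5305 were higher and 3143 lower, and with FPKM as deposited 2809 were higher and 4077 lower, after a shift of the median of all genes by -0.18.

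**Figure D4:**
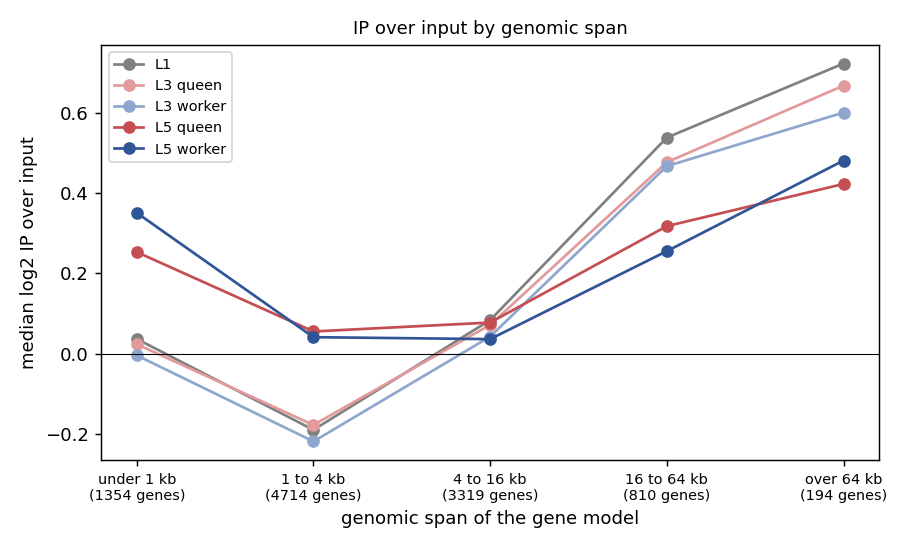
Median log2 ratio of IP to input by the genomic span of the gene model, for the 5 kinds of larvae (mean of 2 replicates per gene, number of genes under each class). Models over 64 kb lie at 0.72 at L1 and at 0.42 and 0.48 in L5 queens and workers, and models under 1 kb at 0.25 and 0.35 in L5 queens and workers.

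Between the castes, the count of genes past the threshold for m6A enrichment depended on the setting. At L3 limma called 0 of 10391 genes (100 at an unadjusted p under 0.05, smallest adjusted p = 0.115), 7 with the L1 and L3 libraries alone, 10 with a weight per library, 6 with no filter on low values and 1 with a pseudocount of 0.1. Without any difference, a share of 0.05 of the genes would be expected at that unadjusted p. The 100, and the 396 of the interaction below, fell short of it. At L3 the median SE of the pooled fit was 0.398, above the SD of the log2 differences of all genes, 0.319. The pooled spread was thus too wide for this comparison, and its 0 does not show that the castes were alike. In simulated data the pooled fit at L3 recovered 6.19% of changes of 1 log2 unit and 90.7% of changes of 3. The smaller changes were recovered at 22.9% with the L1 and L3 libraries alone (5.88% of calls false) and at 28.9% with a weight per library (10.4% false). It called 1 without L3 worker replicate 2 or without either L5 queen replicate, and 3 without either L5 worker replicate. At L5 it called 11, 3 higher and 8 lower in queens, among them GB50161 (Group15.19, 957448 to 957973, plus strand) and GB41400 (Group9.4, 233097 to 233777, minus strand), which were higher, and GB46849 (Group3.5, 693396 to 693718, minus strand, overlapping another model) and GB52577 (GroupUn74, 147022 to 148654, plus strand), which were lower. In 7 of the 11 (63.6%), at least 1 of the 8 libraries was listed at 0, against 16.9% of all genes tested. GB46849 and GB52577 were listed at 0 in both L5 worker input libraries, so no fold is given. The IP of GB50161 was 5.32 and 5.00 FPKM in L5 queens against 4.51 and 3.72 in workers. Its input was 1.01 and 2.34 against 12.1 and 9.55. For GB41400 the IP was 2.77 and 1.95 against 2.51 and 2.41. Its input was 0.518 and a value listed at 0 against 3.63 and 4.33. Both calls thus rest on low input in L5 queens more than on IP. The calls of GB50161 and GB41400, at a limma adjusted p of 4.89e-02 each, were lost without any one L1 or L3 replicate, and those of GB46849 and GB52577 without either L3 queen replicate (0.0600 and 0.0602). With a pseudocount of 0.1 limma called 92 (30 higher, 62 lower) and with no filter 89 (45 higher, 44 lower). With the L5 libraries alone or a weight per library limma called 0. In simulated data 49.1% of the calls of the pooled fit were false, while the fit of the L5 libraries alone recovered 0% of changes of 1 log2 unit and 75% of changes of 3. The count was 1 without either L3 queen replicate, 4 without either L3 worker replicate, 110 and 49 without L5 queen replicates 1 and 2, and 206 and 27 without L5 worker replicates 1 and 2. On the FPKM as deposited 1 gene was higher and 9 lower. The interaction of caste and instar gave 0 genes (396 at an unadjusted p under 0.05), 19 with a pseudocount of 0.1, 9 with no filter, 29 and 7 without L5 queen replicates 1 and 2, and 20 and 4 without L5 worker replicates 1 and 2.

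From L1 to L3, limma called 0 genes for m6A in queens (97 at an unadjusted p under 0.05; 1 without L1 replicate 1 or either L5 worker replicate) and 2 in workers. GB55717 (Group6.38, 701641 to 702345, plus strand) had 131 and 136 FPKM in L3 worker IP against 280 and 258 in input, and at L1 150 and 124 in IP against 41.6 and 38.5 in input, a log2 change of -3.06 ± 0.28 (SE, n = 2 and 2, limma adjusted p = 3.72e-04). This call rests on the rise of input more than on IP. GB50446 (Group4.9, 13135 to 13316, plus strand) had 29.2 and 29.2 FPKM in L3 worker IP with both inputs listed at 0, and its call was lost without any one L1 or L3 worker replicate (limma adjusted p of 0.250 to 0.660). The queen count was 4 with no filter, and 2 with the L1 and L3 libraries alone or a weight per library. The worker count was 13 with the L1 and L3 libraries alone, 21 with a weight per library, 4 with no filter or with FPKM as deposited, 1 without L1 replicate 2, 5 without either L5 worker replicate, and 0 without L3 worker replicate 1, which ended the call of GB55717 (limma adjusted p = 0.0515).

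From L3 to L5 the IP over input ratio changed in many genes of both castes. GB53599 (Group10.10, 247388 to 250313, plus strand, overlapping another model) had 765 and 573 FPKM in L3 queen IP against 21.5 and 16.3 in input, and 15 and 10.5 in L5 queen IP against 8.29 and 8.67, a log2 change of -5.02 ± 0.69 (SE, n = 2 and 2, limma adjusted p = 6.36e-04). GB45146 (Group11.18, 2249621 to 2253071, plus strand, overlapping another model) had 7.07 and 7.52 FPKM in L3 worker IP against 7.33 and 7.71 in input, and 7.13 and 5.46 in L5 worker IP against 207 and 60.3. Its fall rests on the rise of input more than on IP. GB55636 (Group2.19, 2512398 to 2513189, plus strand) also fell in queens, but its L5 queen input was 14 and 213 FPKM. Its call was lost without L5 queen replicate 2 (limma adjusted p = 0.0865), L3 queen replicate 1 or 2 (0.162 and 0.129) or L3 worker replicate 1 or 2 (0.0537 and 0.0540). Among the genes that rose, GB54055 (Group11.12, 142603 to 142857, plus strand) and GB55246 (Group11.6, 1401142 to 1402272, plus strand) were listed at 0 in both L5 queen input libraries. The call of GB54055 was lost without any one L1, L3 or L5 queen replicate (limma adjusted p of 0.0539 to 0.182). GB54979 (Group1.41, 75936 to 76859, plus strand, overlapping another model) was listed at 0 in both L3 worker IP and both L5 worker input libraries. GB50351 (Group1.3, 17920 to 18461, plus strand) had 0.748 FPKM and a value listed at 0 in L3 worker IP against 6.74 and 8.77 in input, and 7.15 and 5.61 in L5 worker IP against 3.12 and a value listed at 0; its call was lost without L3 worker replicate 2 (limma adjusted p = 0.0659). GB50849 (Group2.11, 1575238 to 1576521, plus strand), among those that fell, was listed at 0 in both L3 worker input and both L5 worker IP libraries. Without L3 worker replicates 1 and 2 the limma adjusted p was 0.0558 and 0.0679 for GB54979 and 0.0517 and 0.0523 for GB50849.

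The change passed for 1951 genes in queens (907 higher, 1044 lower) and 1364 in workers (629 higher, 735 lower), by limma at an adjusted p under 0.05. At least 1 of the 8 libraries was listed at 0 for 161 and 189 of them. These were 8.25% and 13.9% of the calls, against 12.8% and 14.6% of all genes tested. Both castes shared 367 genes that rose and 584 that fell, against 54.9 and 73.8 for independent lists. The log2 changes correlated at r = 0.75 across genes. The L3 ratios of queens and workers correlated at 0.925 to 0.931, and subtracting such similar ratios makes the changes correlate even without a shared change at L5. Independent lists are thus only a reference, and the excess was not tested. In queens the count was 493 and 448 without L3 queen replicates 1 and 2, 1257 and 1248 without L3 worker replicates 1 and 2, and 930 with a weight per library. In workers it was 57 and 49 without L3 worker replicates 1 and 2, 2191 and 2187 without L5 queen replicates 1 and 2, and 794 without L5 worker replicate 1. The shared calls in the same direction, 951 in all, numbered 378 and 353 without L3 queen replicates 1 and 2, 43 and 39 without L3 worker replicates 1 and 2, and 514 without L5 worker replicate 1. With FPKM as deposited the splits were 2000 higher and 603 lower in queens and 1390 higher and 288 lower in workers, after shifts of the median of all genes by 0.39 in queens and 0.42 in workers. With no filter 1213 genes were higher and 745 lower in workers. In simulated data 16.8% of the queen calls and 11.3% of the worker calls were false.

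Changes in expression and in m6A enrichment were related across genes with no library shared, taking the input change from 1 replicate number and the enrichment change from the other. Spearman's rho, the mean of both assignments over 10391 genes, was -0.0787 between L3 castes, -0.0780 between L5 castes, -0.0149 from L1 to L3 queens, -0.0782 from L1 to L3 workers, 0.00369 from L3 to L5 in queens and -0.00618 in workers. With FPKM as deposited it was -0.167 between L3 castes, -0.0892 from L1 to L3 queens, -0.169 from L1 to L3 workers, and -0.0282 and -0.0231 from L3 to L5 in queens and workers. With a pseudocount of 0.1 it was -0.0452 from L1 to L3 queens, and -0.0448 and -0.0508 from L3 to L5 in queens and workers. Both settings turned the sign from L3 to L5 in queens. With the same libraries on both sides it was -0.175 to -0.637, a value that the shared input forces below 0. The 2 assignments differed in sign from L1 to L3 queens (-0.0486 and 0.0187) and from L3 to L5 in queens (-0.0198 and 0.0272) and workers (-0.0201 and 0.0077). Between L5 castes they were -0.0329 and -0.123. The ratios of single replicates are noisy, with a replicate r of 0.357 in L5 queens and 0.454 in L5 workers. Noise weakens rho, so a weak rho does not exclude a relation.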

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

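The difference between the castes changed between instars 3 and 5 by a test of the interaction, for 808 genes at a limma adjusted p under 0.05. Of these, 271 had passed between castes at L3 alone, 359 at L5 alone, 60 at both instars in opposite directions, 38 at both in the same direction and 80 at neither. This breakdown rests on the pooled fit, whose 1150 calls between L5 castes fell to 77 with the L5 libraries alone. Among the genes chosen by the rule, the interaction was 7.38 for GB47565, 6.45 for GB50662, -6.85 for GB42557 and -5.92 for GB48098 on the log2 scale, with positive values for genes whose queen minus worker difference was higher at L5. For GB47565 and GB50662 the L3 queens stood near L1 while the L3 workers and both L5 castes were higher, for GB42557 the L5 queens stood apart from the other larvae, and for GB48098 the castes swapped places.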

How the results depend on the processing

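The fits on L1 and L3 libraries alone, on L5 libraries alone and with a weight per library were chosen after seeing the data. Of the 46 results on single named genes, none turned its direction in the alternatives run: 239 of 256 values kept their call outside the omission of replicates and 17 lost it, and with 1 replicate left out 416 of 460 kept it and 44 lost it. The cause of the changes below was not tested, except that a fit with fewer libraries has fewer degrees of freedom. Depth is unknown, so its limit on low genes could not be set. The tests of the gene lists with an estimated correlation and with fry were not run, since no ID matched a name.

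With 1 replicate left out, the other library of that group is assumed to vary like the other groups. The counts for expression then ran from 253 to 1177 between L3 castes, 640 to 1746 between L5 castes, 178 to 1762 for the caste difference between instars, 331 to 1289 for L3 queens against L1, 721 to 2750 for L3 workers against L1, 2703 to 5034 for L5 against L3 in queens and 1853 to 4654 in workers. For m6A they ran from 6172 to 7113 for IP against input, 0 to 3 between L3 castes, 1 to 206 between L5 castes, 0 to 29 for the caste difference, 0 to 1 for L3 queens and 0 to 5 for L3 workers against L1, 448 to 2424 for L5 against L3 in queens and 49 to 2191 in workers. Shared calls ran from 66 to 274 between instars, 1378 to 2755 between castes and 39 to 1223 between castes for m6A. L5 minus L1 and L3 ran from -0.368 to -0.258 for the SD of the log2 ratio of IP to input, 28.2 to 32.4 percentage points for silent genes above 0 and 1541 to 1920.0 for models at 0.

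With FPKM as deposited, the counts were 2944 between L3 castes, 1338 for the caste difference between instars, 5972 for L3 workers against L1 and, for m6A, 4 for L3 workers against L1. The rho of expression change and m6A change moved to -0.167 between L3 castes, -0.0892 for L3 queens against L1 and -0.169 for L3 workers against L1. With no filter on low values the m6A counts were 6 between L3 castes, 89 between L5 castes, 9 for the caste difference, 4 for L3 queens against L1 and 4 for L3 workers. With a pseudocount of 0.1 the m6A counts were 1 between L3 castes, 92 between L5 castes and 19 for the caste difference, and rho moved to -0.0448 for L5 against L3 in queens and -0.0508 in workers. The SD of the log2 ratio of IP to input, lower by -0.311 at L5, then differed by 0.0237 the other way (exact permutation p = 0.743).

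With the L1 and L3 libraries alone, the counts were 2381 between L3 castes, 2231 for L3 queens and 4155 for L3 workers against L1, and for m6A 7, 2 and 13 in the same order. With the L5 libraries alone they were 77 for expression and 0 for m6A between L5 castes. With a weight per library they were 3012 between L3 castes, 124 between L5 castes, 390 for the caste difference, 2050 for L3 queens and 4519 for L3 workers against L1, and for m6A 10 between L3 castes, 0 between L5 castes, 2 for L3 queens and 21 for L3 workers against L1 and 930 for L5 against L3 in queens, with 70 caste calls shared between instars.

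The libraries share replicate numbers, but the labels do not say what a number marks. Deviations of IP and input with the same number correlated at r = 0.646 in L1, 0.634 in L3 queens, 0.163 in L3 workers, 0.426 in L5 queens and 0.0793 in L5 workers, and same-numbered input libraries of different groups at -0.0256 to 0.365. All 5 pairs of IP and input were positive, a hint from the data and not from the design, but 1 was under 0.1, so the numbers were not used as pairs in the tests of genes. Ratios of single libraries, and the values drawn from them, did set IP against the input of the same number. With the number as a replicate block, the m6A counts were 79 between L5 castes, 1 for L3 workers against L1, 3650 for L5 against L3 in queens and 3019 in workers, with 2206 shared between castes. Counts for expression stayed within 1.5 times. These counts were printed together with the check of the pairs.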

Other observations

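The test of sequencing depth, the control for span and the comparison of library measures were chosen after the results were seen, as was reading the L5 castes apart. On scaffold Group12.10 the 5 models from 93729 to 105829 summed to 14.1 and 15.3 FPKM at L1, 2454 and 1056 in L3 queens, 30.9 and 34.0 in L3 workers, 67732 and 111337 in L5 queens and 29170 and 30495 in L5 workers. On Group10.13 the 5 models from 115066 to 153665 summed to 93 and 98.4 FPKM at L1, 647 and 559 in L3 queens, 3510.0 and 4112 in L3 workers, 724 and 1009 in L5 queens and 1819 and 1096 in L5 workers. GB49775 (Group2.18, 411953 to 419310, minus strand), chosen after its values were seen, had 990.3 FPKM in L5 worker input replicate 1 and 46548 in replicate 2, and 969 and 569 in the IP libraries of the same larvae.

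The L1 and L3 larvae (n = 6 libraries of a kind) and the L5 larvae (n = 4) were compared in 3 measures. Each gave an exact two-sided permutation p of 0.00476, the smallest this design can give (0.00476 adjusted over the 3). The test treats the libraries as exchangeable, though they are 2 replicates for each of 5 kinds of larvae and replicates may be technical. Its p therefore describes these libraries only, and not a difference between instars in general. The SD across genes of the log2 ratio, taken between IP and input of the same number, was 1.09 ± 0.0302 (SD, n = 6) and 0.780 ± 0.135 (SD, n = 4). This difference of -0.311 did not hold with a pseudocount of 0.1, where it was 0.0237 (exact permutation p = 0.743). Of 2810 genes with a mean input FPKM under 0.1, 21.8% ± 8.29 and 52.2% ± 4.67 were listed above 0 in IP. Models listed at 0 in input numbered 3305 ± 324 and 4992 ± 491.

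The profile of IP over input at L5 departed from that at L1. If reads spread over all models were the source, 803 genes above 50 FPKM in input should have kept the L1 profile at r of at least 0.8, but in L5 queens r was 0.419, below this by more than the difference between replicates. In L5 workers it was 0.675, and the replicates, at 0.518 and 0.673, were too far apart to decide. Random error alone should leave r, corrected for the replicates' own correlation, at 0.9 or more: it was 0.488 in queens (0.406 to 0.572 over choices of replicates), and 0.756 in workers (0.641 to 0.867). All choices in workers lay under 0.9, but the mean fell short of it by less than the width of their range, the margin set before the test, so error stays open there. A change of m6A between instars remains a hypothesis, as do differences in how the libraries were made, for which the labels give no batch.

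Genes silent in input were listed above 0 more often in the L5 IP libraries. Deeper sequencing should leave their mean FPKM within the range of L1 and L3, 0.0460 to 0.123, but the lowest L5 library had 0.208. An even background was predicted to give a rho under 0.3 across these genes between castes, a limit not derived from a model of background. The mean rho over pairs of single libraries was 0.556. Between the means of the replicates it was 0.660, and within 10 bins of span its median fell to 0.617 (0.521 to 0.771). Span here is genomic. Other traits of a model that are the same in every library, such as the length of its exons, were not controlled and could also raise rho. The test therefore cannot separate a background from a source of RNA particular to these genes, and both stay open.

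Between L3 castes, the queen minus worker difference was weakly and negatively related across genes to the change from L1 to L5. Spearman's rho across genes between the L3 queen minus worker difference and the L5 minus L1 difference was -0.183 and -0.266 for replicates 1 and 2. A trend with abundance should vanish within bins of abundance, but the median rho over 10 bins was -0.284 (-0.418 to -0.0198, with 8 of 10 bins below -0.1). That L3 workers stood further along that change than L3 queens, and changes of genes particular to a caste, both stay open and cannot be told apart, since the rho is the pattern itself and no other value here decides.

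For IP against input, 1 of 100 splits of the 20 libraries into 10 and 10, the real one, gave as many genes. In this fit the real split gave 6556 genes and the highest other 3531, with 8 of the 10 IP libraries on one side. Splits that mix IP and input add their difference to the spread, and 96 of the other splits gave no gene. The real split was thus bound to rank first, so its rank decides nothing about the source of the difference.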
